A study of Homo sapiens with 14 samples.

How the data were processed

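Gene expression was measured by RNA sequencing in HepG2, a human hepatoma cell line, in a line that overexpresses BHMT (OE) and a line in which BHMT is knocked out (KO). Both lines were measured as cultured cells, with 3 libraries per group, and as tumors grown in nude mice, with 4 libraries per group. Per the labels' protocols, the cells had spent 48 h in human plasma-like medium (HPLM), and the OE cells had received blasticidin for 48 h, 1 week before extraction. Per the same protocols, RNA of the tumors was obtained after cryogenic milling with a kit for fibrous tissue, and all libraries were stranded total RNA libraries depleted of ribosomal RNA. Samples were grouped by the OE or KO and the cell or tumor wording of their labels, and the column names of both tables matched these labels 1 to 1.

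The authors deposited 1 table for the cells and 1 for the tumors, each holding estimated counts per gene symbol and library, already whole numbers. Per the submitters' processing notes, kallisto, the build GRCh38, R 4.1.0 and DESeq2 1.33.1 were used, while the kallisto version, the transcript annotation and the way transcripts were reduced to 1 row per symbol are not given in the sources used here. The cell table had 9947 rows with a symbol and 1 row without, which held 0.00132% of counts and was left out, and the tumor table had 12937 rows. Every row of both tables had at least 1 count in every library, so genes without counts in some library were not analysed here. Per the file headers the authors also deposited a mean signal, which was the mean of the counts divided by 1 size factor per library to within 4.94e-10 of its value. The deposited log2 fold change was that of OE over KO, while the deposited Wald score had the opposite sign in all 9947 and 12937 rows, and the deposited p-value and adjusted p-value columns belong to that score. These columns of the authors were used only for a comparison of calls.

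Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, libraries were scaled by trimmed means of M values (TMM), and OE was tested against KO by edgeR's quasi-likelihood test with robust dispersions, 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Cells and tumors were fitted separately, and the difference of their OE against KO effects was tested as an interaction in 1 fit over all 14 libraries and the genes in both tables. Expression levels (CPM) are counts per library total, scaled by the TMM factors, and errors are standard deviations (SD) over libraries or standard errors (SE) of the fit. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes, over lists with at least 5 members tested, and again with an estimated correlation and with fry, which tests whether the genes of a list move, on balance, one way. Single values were compared by exact permutation tests, 2-sided, which cannot go below 0.1 for 3 against 3 libraries or below 0.0286 for 4 against 4.

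The design, the tests, 35 gene lists and the rule for named genes were fixed before the data were examined. BHMT was named first and kept out of lists and rankings. In each OE against KO comparison, the 10 highest and 10 lowest log2 fold changes were named among genes past the threshold, with an average log2 CPM of at least 2 and no overlap between the groups. From each list, up to 4 members past the threshold were named by adjusted p, and where fewer than 2 passed, up to 2 members with the highest average expression. Some genes that this rule names are not reported here. Between the comparisons, the rule took the 8 genes called in both with the same sign and the 6 with opposite signs that had the largest smaller change, and for the difference of effects the 5 highest and 5 lowest. The lists cover methyl group metabolism (methionine cycle and transsulfuration, folate, choline and betaine, polyamines, methylation enzymes, genes silenced by DNA methylation, imprinted genes), stress responses, lipid and liver functions, growth, inflammation and respiration. They also cover markers of fibroblasts, endothelium, leukocytes, skeletal muscle, adipocytes, erythroid cells and keratinocytes, which a tumor in a mouse could hold.

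Coordinates, transcript numbers and GC contents were taken from GENCODE 29 on GRCh38. Of the 14873 symbols found in at least 1 of the 2 tables, 14395 were matched by symbol, 415 by gene ID and 63 were unmatched. Genes were grouped along chromosomes in bins of 10 Mb. In simulated counts drawn from the real means, edgeR's quasi-likelihood test recovered 58% of 100 genes changed 2-fold and 84% of 100 changed 4-fold in the cell design of 9490 genes. The tumor design of 11300 genes recovered 2% and 45%, and the difference in 8008 genes 1% and 29%. False calls made up 4.68%, 4.08% and 6.25% of all calls in these simulations, and a changed proliferation list was recovered in each, while 1 unchanged list was called in the cell design, 1 in the tumor design and 0 in the difference. Genes were drawn independently of each other and 1 time per design, so these rates do not cover genes that vary together between libraries. For the difference, each gene had 1 dispersion for all 14 libraries. The coefficient of variation between libraries was 0.216 in cells and 0.414 in tumors, and the rates of the difference do not cover this unequal spread.

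Alternatives were other scalings (median-ratio factors, library size alone), DESeq2 1.42.0, voom of limma, other count filters, thresholds, designs and sets of libraries, and their effect is given at the end. Total counts ranged from 10830526 to 13382570 per cell library and from 3269865 to 7235182 per tumor library, so tumor libraries held fewer counts per gene. Between libraries of a group, the chi-square of their counts per gene was at least 9.01, where sampling noise alone gives about 1, so each library was counted as 1 sample. The labels do not say that replicates were separate cultures or animals, so p-values measure the spread between these samples, which may be technical. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.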

Results

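BHMT, betaine-homocysteine methyltransferase, is a liver enzyme that makes methionine from homocysteine with betaine as the methyl donor. RNA was measured in HepG2 hepatoma cells that overexpress BHMT (OE) or lack it (KO), once as cultured cells (3 OE and 3 KO libraries) and once as tumors in nude mice (4 OE and 4 KO libraries). The cell libraries held 10830526 to 13382570 counts and the tumor libraries 3269865 to 7235182 counts. In cells, libraries of the same group correlated across genes with r from 0.973 to 0.977 and libraries of different groups with r from 0.953 to 0.959. In tumors these ranges were 0.800 to 0.928 and 0.732 to 0.911. Tumor OE replicate 4 correlated with the 4 KO tumors at r from 0.890 to 0.911, and with OE replicates 1, 3 and 5 at 0.902, 0.800 and 0.856. Log2 fold changes are those of OE over KO throughout, and no line with unmodified BHMT was analysed here. Each table holds 1 row per gene symbol, and a row may stand for part of a gene's transcripts, since the way transcripts were combined is not given in the sources used here.

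BHMT (ENSG00000145692.14, chromosome 5, 79111779 to 79132290 on the plus strand of GRCh38) separated the groups in both systems. In cells, its level was 2183 ± 900 CPM in OE and 0.667 ± 0.371 CPM in KO (SD, n = 3 each), a log2 fold change of 11.68 (SE 0.59). The 3 KO cell libraries held 3, 9 and 11 BHMT counts, and the 3 OE libraries 33498, 34379 and 14794. In tumors, the level was 2928 ± 1192 CPM in OE and 9.42 ± 7.18 CPM in KO (SD, n = 4 each), a log2 fold change of 8.29 (SE 0.60), with 14 to 70 counts per KO library. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p was 3.8e-05 in cells and 5.9e-05 in tumors, and exact permutation tests gave their smallest possible values, p = 0.1 and p = 0.0286. The BHMT effect was smaller in tumors than in cells by a log2 difference of -3.41 (SE 0.80, adjusted p = 0.0262 by the same edgeR test). The OE mean was not lower in tumors than in cells (2928 against 2183 CPM), whereas the KO mean was higher (9.42 against 0.667 CPM). With voom of limma the cell call was lost (adjusted p = 0.0779, against a range of 6.0e-74 to 0.0779 over 15 alternatives, with log2 fold changes from 11.26 to 12.01). In the authors' deposited table, the BHMT log2 fold change was 11.68 in cells and 8.30 in tumors.

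**Figure D1:**
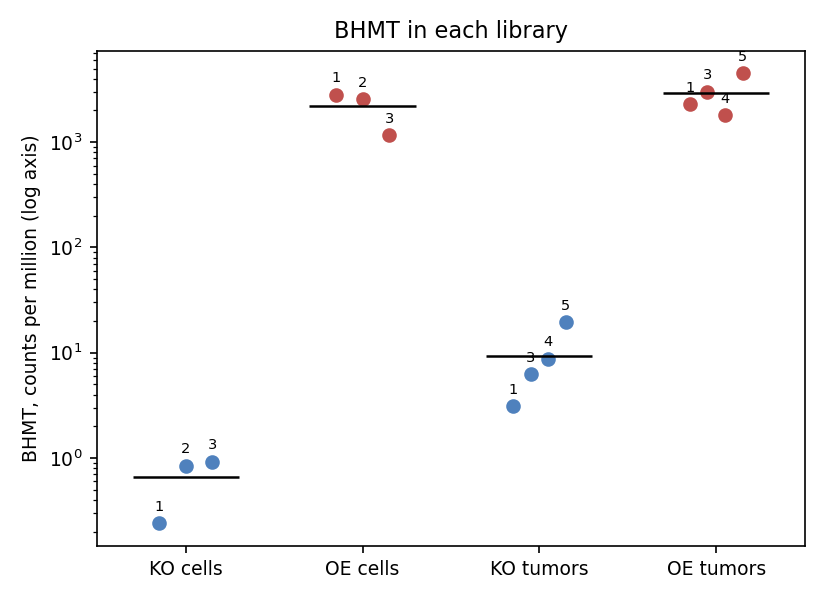
BHMT level in CPM (log axis) in each library of the 4 groups; points are libraries with their replicate numbers and lines are group means. The OE libraries of both systems lie at 1159 CPM or above and the KO libraries at 19.4 CPM or below.

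Some genes near BHMT were higher in OE cells. There, 3 of the 5 genes tested within 500 kb of BHMT rose, namely BHMT2, a neighbouring methyltransferase gene (log2 fold change 2.60, SE 0.13), LHFPL2 (1.07, SE 0.13) and ARSB (0.59, SE 0.04). Of all 9490 genes tested in cells 888 rose, and 19.7% passed in either direction. In tumors 1 of 7 rose, where 62 of all 11300 genes did. It was DMGDH, which encodes dimethylglycine dehydrogenase and lies over BHMT on the opposite strand (2.93, SE 0.50), while BHMT2 had -0.04 (SE 0.30). The adjusted p-values of edgeR's quasi-likelihood test were 1.92e-05, 0.00151 and 9.28e-05 in cells and 0.0203 for DMGDH in tumors. Of the 3230 stretches of 31 bases of BHMT2, 148 also occur in BHMT on the same strand, so its counts are uncertain. DMGDH shares 187 of 5336 with BHMT, all on the opposite strand and in 2 processed transcripts, and 0 on the same strand, and whether reads were assigned by strand is not given in the sources used here, so its counts are uncertain too. The DMGDH call was lost without OE replicate 3 or 5 or KO replicate 1, 3 or 4 (adjusted p = 0.0604, 0.0853, 0.0555, 0.0610 and 0.0642 by edgeR).

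The first comparison asked how cultured OE and KO cells differ in expression. The lowest genes in OE were MYL9, a myosin regulatory light chain (ENSG00000101335.9, chromosome 20, 36541484 to 36551447), at 0.394 ± 0.338 against 84.1 ± 7.37 CPM (SD, n = 3 each, log2 fold change -7.70, SE 0.33), and GPC3. GPC3, a cell surface proteoglycan often present in liver tumors (ENSG00000147257.13, chromosome X, 133535745 to 133985895), stood at 0.620 ± 0.454 against 118 ± 13.6 CPM (-7.53, SE 0.31). CDO1, the cysteine dioxygenase that commits cysteine to taurine and sulfate (ENSG00000129596.4, chromosome 5, 115804733 to 115816954), fell from a mean of 125 CPM in KO to 1.46 CPM in OE (-6.40, SE 0.26, n = 3 each). The highest gene after BHMT was SSTR5, a somatostatin receptor (ENSG00000162009.8, chromosome 16, 1078781 to 1080142), at 34.2 ± 2.55 CPM in OE and 1.02 ± 0.605 CPM in KO (5.07, SE 0.36). HOXD4, a homeobox factor of body patterning (ENSG00000170166.5, chromosome 2, 176151222 to 176153226), was at 29.1 ± 6.11 against 1.75 ± 0.607 CPM (4.05, SE 0.31).

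The other 8 genes with the highest changes in cells were IRX3, a homeobox factor, FCHSD1, NT5E, an ectoenzyme that makes adenosine, ARFGEF3, CARMIL1, NRCAM, a cell adhesion protein, B4GALNT4 and LPCAT2, with log2 fold changes from 2.90 to 3.88. The other 7 with the lowest were KCNC1, a potassium channel, LIPH, DPYS, an enzyme of pyrimidine breakdown, SORCS2, UBD, a ubiquitin-like protein, CDK14 and MAF, with log2 fold changes from -5.44 to -4.50. In all 20, each OE library lay above or below each KO library, which the naming rule required. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, their adjusted p ranged from 6.32e-07 for UBD to 0.00272 for NT5E. All 20 also passed in each of the 6 fits that left out 1 cell library.

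Across the cells, 1870 of 9490 genes passed edgeR's quasi-likelihood test, 888 higher and 982 lower in OE, and 465 of them changed at least 2-fold. With all 14 libraries in 1 fit 172 of 8008 genes passed in cells, and 85 of the 130 named cell genes in that fit lost their call. The groups did not overlap in 3644 genes (38.4%, where chance gives 10%). By the authors' deposited values 1660 genes passed, 734 higher and 926 lower, and 1541 of them were among the 1870. Of the 35 lists, 29 had enough members for a test in cells and 17 passed camera with the preset correlation, while 0 of 29 passed with an estimated correlation, 5 had an unadjusted p below 0.05 there, and 18 passed fry. Per the labels the OE cells had received blasticidin 1 week before extraction, so an effect of the drug was not separated from that of BHMT.

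**Figure D2:**
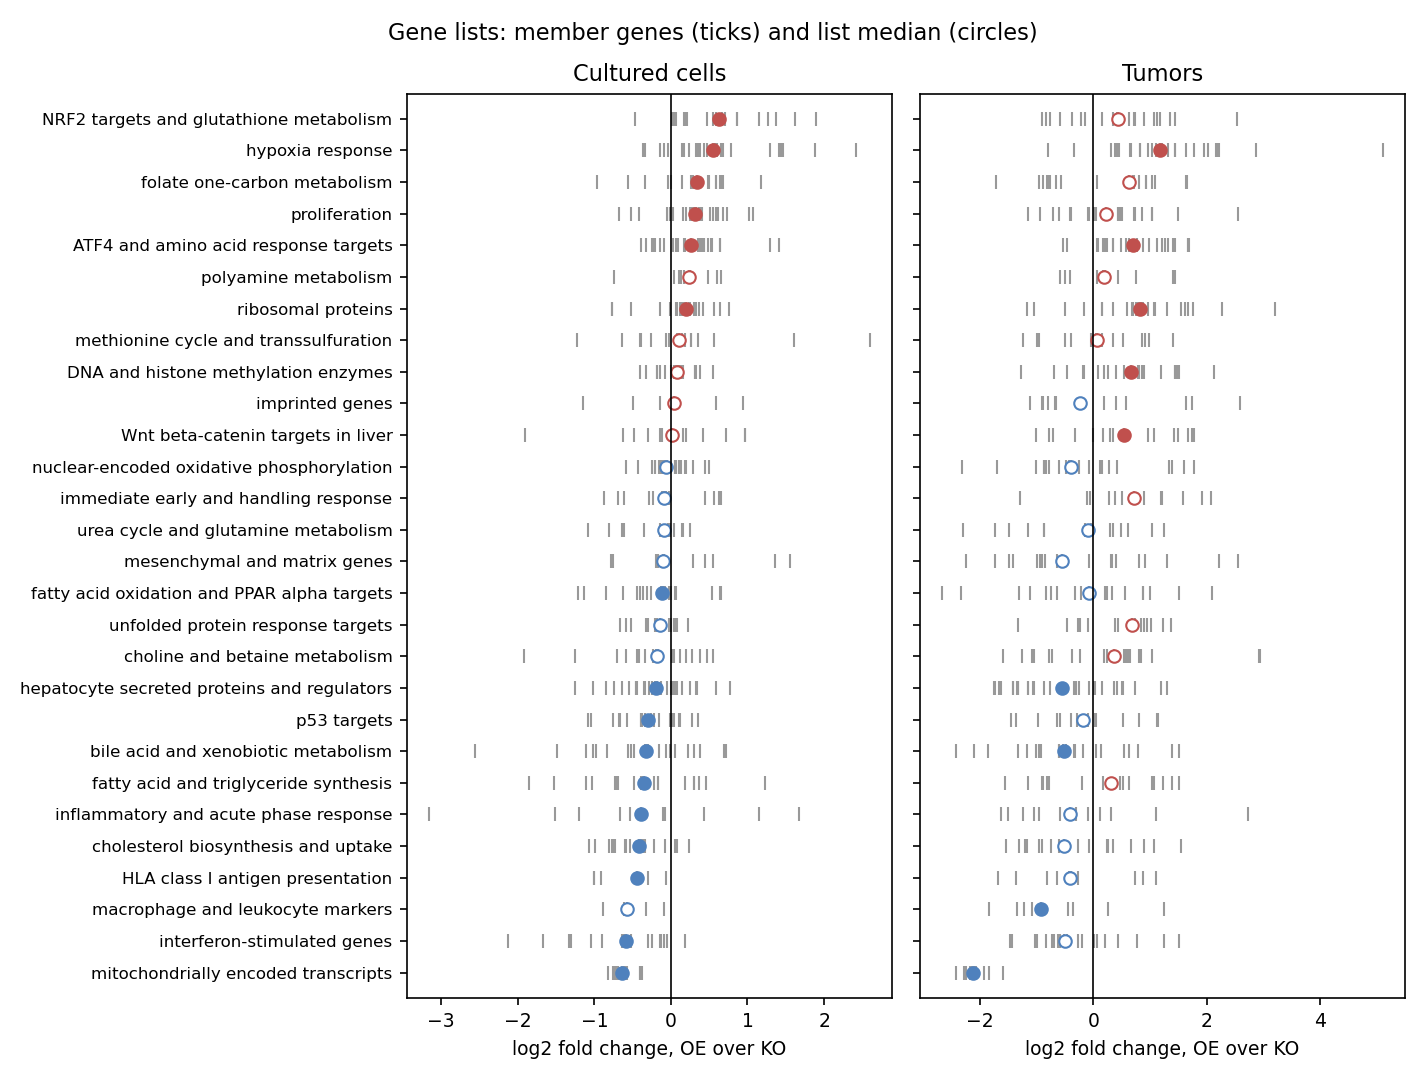
Log2 fold change (OE over KO) in cells and in tumors of the members of the gene lists that had a list test in both. Ticks are genes, and circles are list medians, red for positive and blue for negative medians. Circles are filled where the camera adjusted p of the list is below 0.05. Mitochondrially encoded transcripts lie lowest in tumors, with a median of -2.11.

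Lists that rose in OE cells were led by targets of NRF2, the regulator of the antioxidant response. Of its 20 members tested 14 rose and 1 fell (14 and 1 adjusted over the list alone), with a median log2 fold change of 0.63 (camera adjusted p = 9.1e-34, and adjusted p = 0.0512 with an estimated correlation). Examples were the reductases AKR1B10 (1.89, SE 0.04), AKR1C2 (1.62, SE 0.08), AKR1C3 (1.37, SE 0.05) and NQO1 (1.15, SE 0.05). Proliferation genes rose in 18 of 30 cases and fell in 0 (19 and 0 adjusted over the list alone, median 0.31). They included the replication helicase subunits MCM2 (0.51, SE 0.04), MCM5 (0.73, SE 0.10) and MCM6 (0.59, SE 0.05) and the mitotic kinase PLK1 (0.56, SE 0.05). The camera adjusted p was 6.5e-07, and adjusted p = 0.174 with an estimated correlation. Hypoxia response genes rose in 8 of 29 cases and fell in 0 (8 and 0 adjusted over the list alone, median 0.55, camera adjusted p = 5.0e-04, adjusted p = 0.464 with an estimated correlation). The glycolytic genes were among them, ALDOC (2.42, SE 0.26), ENO1 (0.61, SE 0.11) and GAPDH (0.43, SE 0.08). ATF4 and amino acid response targets rose in 4 of 25 cases and fell in 0 (3 and 0 adjusted over the list alone, median 0.27, camera adjusted p = 0.0187, adjusted p = 0.464 with an estimated correlation). The cystine transporter SLC7A11 (1.41, SE 0.12) and the arginine transporter SLC7A1 (0.64, SE 0.08) rose. Neither the hypoxia list nor the ATF4 list passed fry (adjusted p = 0.0739 and 0.0640). Ribosomal protein genes rose in 9 of 27 cases and fell in 1 (12 and 1 adjusted over the list alone, median 0.20, camera adjusted p = 0.0093, adjusted p = 0.174 with an estimated correlation). RPS14 had 0.65 (SE 0.11) and RPS23 -0.77 (SE 0.11).

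Metabolism of methyl groups, the setting of BHMT, moved in parts. Of the 18 folate genes tested in cells 8 rose and 1 fell (9 and 1 adjusted over the list alone, median 0.34, camera adjusted p = 0.0255, adjusted p = 0.174 with an estimated correlation, and 0.0554 without OE replicate 3). The folate carrier SLC19A1 (0.68, SE 0.08), SHMT2 (0.34, SE 0.05) and ATIC (0.27, SE 0.04) rose, and GGH (-0.56, SE 0.06) fell. The list of the methionine cycle and transsulfuration did not pass camera (median 0.11, adjusted p = 0.138), with 4 of 18 members higher and 2 lower (6 and 2 adjusted over the list alone). By fry this list passed, pointing up (adjusted p = 0.00667). BHMT2 led it, and GNMT, which consumes S-adenosylmethionine, fell (-1.23, SE 0.20). Choline and betaine genes had 2 higher and 4 lower of 19 (4 and 5 adjusted over the list alone, median -0.18, camera adjusted p = 0.315), with ETNPPL at -1.91 (SE 0.16). By fry they passed, pointing down (adjusted p = 0.0347). Polyamine genes had 3 higher and 1 lower of 11 (4 and 1 adjusted over the list alone, median 0.23, camera adjusted p = 0.154), with ODC1 at 0.25 (SE 0.04). DNA and histone methylation enzymes had 1 higher of 21, KDM1A at 0.31 (SE 0.06), and 0 lower (1 and 0 adjusted over the list alone, median 0.08, 0.486). Imprinted genes had 0 changed of 7 by edgeR's quasi-likelihood test and 0 adjusted over the list alone, with a median of 0.03, a mean of -0.03 and a camera adjusted p of 0.915. No gene of the list silenced by DNA methylation was tested in cells.

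Lists that fell in OE cells held mitochondrially encoded transcripts, lipid synthesis and liver functions. Of the 13 mitochondrially encoded transcripts 0 rose and 11 fell (0 and 13 adjusted over the list alone), with MT-CO1 at -0.76 (SE 0.08), MT-CO2 at -0.82 (SE 0.13) and MT-CYB at -0.71 (SE 0.11). Their median was -0.63 (camera adjusted p = 4.7e-08, adjusted p = 0.253 with an estimated correlation), and they took 1.95 ± 0.315% of counts in OE and 3.05 ± 0.0687% in KO (SD, n = 3 each). Nuclear-encoded genes of oxidative phosphorylation did not pass (0 higher and 2 lower of 24, 0 and 2 adjusted over the list alone, median -0.07, camera adjusted p = 0.743), with SDHA at -0.59 (SE 0.09). Cholesterol synthesis and uptake genes rose in 0 and fell in 12 of 20 cases (0 and 13 adjusted over the list alone, median -0.42, camera adjusted p = 2.8e-07). MVD (-0.81, SE 0.05) and MSMO1 (-0.77, SE 0.06) fell. Fatty acid and triglyceride synthesis genes rose in 2 and fell in 9 of 20 cases (2 and 11 adjusted over the list alone, median -0.36, camera adjusted p = 9.4e-07), with ACSL1 at -1.85 (SE 0.05) and ACSS2 at -1.11 (SE 0.07). For both lipid lists, adjusted p = 0.174 with an estimated correlation.

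Hepatocyte secreted proteins and regulators rose in 0 and fell in 8 of 30 cases in OE cells (0 and 9 adjusted over the list alone, median -0.19, camera adjusted p = 4.2e-05). Examples were HPD, a tyrosine breakdown enzyme, at -1.02 (SE 0.04), APOE at -0.75 (SE 0.04) and RBP4 at -0.55 (SE 0.04). Bile acid and xenobiotic genes rose in 0 and fell in 6 of 21 cases (1 and 6 adjusted over the list alone, median -0.32, camera adjusted p = 5.8e-04). CYP7A1, the rate-limiting enzyme of bile acid synthesis (-2.55, SE 0.28), and SULT2A1 (-1.10, SE 0.04) fell. Fatty acid oxidation genes rose in 0 and fell in 5 of 20 cases (0 and 7 adjusted over the list alone, median -0.11, camera adjusted p = 0.0197, and 0.169 without OE replicate 3), with SLC25A20 at -1.14 (SE 0.10). For these 3 lists, adjusted p = 0.174 with an estimated correlation. Urea cycle genes did not pass (2 higher and 1 lower of 12, 2 and 2 adjusted over the list alone, median -0.09, camera adjusted p = 0.840). Targets of the unfolded protein response did not pass either (0 higher and 3 lower of 15, 0 and 3 adjusted over the list alone, median -0.14, 0.232), where DNAJB9 had -0.67 (SE 0.09).

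Immune and tissue lists fell as well in OE cells. Interferon-stimulated genes rose in 0 and fell in 6 of 17 cases (1 and 9 adjusted over the list alone, median -0.59, camera adjusted p = 0.0177), with GBP1 at -1.67 (SE 0.26) and HERC5 at -2.13 (SE 0.41). HLA class I genes rose in 0 and fell in 3 of 7 (0 and 6 adjusted over the list alone, median -0.45, camera adjusted p = 0.0239, and 0.0609 without OE replicate 3), with B2M at -0.45 (SE 0.06) and TAPBP at -0.91 (SE 0.17). Inflammatory and acute phase genes rose in 2 and fell in 3 of 11 (3 and 5 adjusted over the list alone, median -0.40, camera adjusted p = 0.0386, and 0.0571 without KO replicate 1). Examples were the chemokine CXCL8 at -3.16 (SE 0.21) and the liver secreted FGL1 at 1.67 (SE 0.30). Skeletal muscle markers rose in 0 and fell in 4 of 6 (0 and 4 adjusted over the list alone, median -1.51, camera adjusted p = 0.0177, and 0.0552 without OE replicate 1), with ACTA1 at -2.24 (SE 0.41) and TNNC2 at -2.26 (SE 0.39). For these 4 lists, adjusted p = 0.174 with an estimated correlation. Targets of p53 rose in 1 and fell in 5 of 20 (1 and 6 adjusted over the list alone, median -0.30, camera adjusted p = 0.0386, adjusted p = 0.268 with an estimated correlation), with TP53INP1 at -0.76 (SE 0.08) and BTG2 at -0.66 (SE 0.09). That call was lost without OE replicate 1, 2 or 3 or KO replicate 1, at 0.0552, 0.0770, 0.0582 and 0.0699.

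The remaining lists did not pass camera in cells. Mesenchymal and matrix genes had 2 higher and 3 lower of 12 (4 and 4 adjusted over the list alone, camera adjusted p = 0.743), with a median of -0.10, a mean of 0.16 and a test pointing down. MMP14 had 1.55 (SE 0.26), FN1 1.36 (SE 0.25) and SPARC -0.78 (SE 0.08). MMP14 lies in the segment of chromosome 14 described below, where 76 of 84 genes were above 0 in cells. Wnt targets had 4 higher and 2 lower of 13 (4 and 2 adjusted over the list alone, camera adjusted p = 0.646), with a median of 0.02, a mean of -0.01 and a test pointing up. LGR5 had 0.72 (SE 0.08) and SLC1A2 -1.90 (SE 0.10). Immediate early genes had 2 higher and 1 lower of 13 (2 and 1 adjusted over the list alone, camera adjusted p = 0.743), with DUSP1 at -0.87 (SE 0.13), and with a median of -0.09, a mean of -0.05 and a test pointing up. Leukocyte markers had 1 lower of 5, CD68 at -0.61 (SE 0.07), and 0 higher (0 and 1 adjusted over the list alone, median -0.58, camera adjusted p = 0.159). By fry they passed, pointing down (adjusted p = 0.0308). Too few members were tested for a list test of fibroblast (2, median -0.44), endothelial (2, -0.20), adipocyte (2, -0.31), erythroid (1, -0.13) and keratinocyte markers (1, 0.04), and of these only ACTA2 (-0.52, SE 0.07) passed.

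The second comparison asked the same of tumors, where 179 of 11300 genes passed edgeR's quasi-likelihood test, 62 higher and 117 lower in OE, all by at least 2-fold. REPS1, an endocytosis adaptor (ENSG00000135597.18, chromosome 6, 138903493 to 138988261), was at 59.1 ± 17.1 CPM in OE and 6.37 ± 0.884 CPM in KO (SD, n = 4 each, log2 fold change 3.21, SE 0.33). PLG, the plasmin precursor made by liver (ENSG00000122194.18, chromosome 6, 160702238 to 160753315), was at 0.738 ± 0.265 CPM in OE and 14.7 ± 5.66 CPM in KO (-4.26, SE 0.48). VEGFA, the angiogenic growth factor (ENSG00000112715.21, chromosome 6, 43770184 to 43786487), was at 273 ± 260 against 7.88 ± 3.27 CPM (5.10, SE 0.77), and the guidance factor SEMA3B at 23.7 ± 2.72 against 2.19 ± 1.42 CPM (3.41, SE 0.44). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p was 0.00166 for REPS1, 0.00308 for PLG, 0.0172 for VEGFA and 0.00816 for SEMA3B.

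The other genes with the highest changes in tumors were IPO5, a nuclear import receptor, CA4, BRD2, METTL9, EARS2, BMP4, a growth factor, and MEGF6, with log2 fold changes from 3.11 to 5.54. The other genes with the lowest were MSH6, a mismatch repair protein, NUMA1, a spindle protein, MTND5P10, PIK3C2G, FAM153CP, CHRDL2, ELMO1, COCH and CDK17, with log2 fold changes from -4.65 to -2.71. MTND5P10 is a pseudogene of the mitochondrial MT-ND5, so its counts are uncertain. Among the 53 named tumor genes that passed besides BHMT, REPS1 and PLG passed in each of the 8 fits that left out 1 library, with adjusted p up to 0.0157 and 0.0233 by edgeR's quasi-likelihood test, and 51 were lost in at least 1 fit. SEMA3B and IPO5 were lost without KO replicate 3 (0.0547 and 0.0610), and VEGFA without OE replicate 5 or KO replicate 3 or 4 (0.0669, 0.0610 and 0.0535).

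The count of 179 tumor genes rested on single libraries. It was 61 without OE replicate 1, 23 without OE 3, 2056 without OE 4, 8 without OE 5, 58 without KO 1, 5 without KO 3, 10 without KO 4 and 164 without KO 5. It was 1, BHMT, with a score of stromal and leukocyte markers as a covariate. Higher genes made up 34.6% of the 179, and 87.0% of 486 under scaling by library size alone, which shifted the median log2 fold change of all tumor genes by 0.30. At unadjusted p below 0.05 there were 2933 genes, DESeq2 called 1220, and the authors' deposited table held 1209, which included all 179. The groups did not overlap in 1501 genes (13.3%, where chance gives 2.86%).

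Of 30 lists tested in tumors 9 passed camera with the preset correlation, 0 passed with an estimated correlation, where 3 had an unadjusted p below 0.05, and 2 passed fry. The latter were ATF4 targets, pointing up, and leukocyte markers, pointing down (fry adjusted p = 0.00778 and 0.00415). Mitochondrially encoded transcripts had the lowest median of the 30. Of 13 tested, 0 rose and 12 fell (0 and 13 adjusted over the list alone), including MT-CYB (-2.42, SE 0.43), MT-ND2 (-2.28, SE 0.43), MT-CO2 (-2.06, SE 0.39) and MT-ND3 (-1.59, SE 0.30). The median was -2.11 (camera adjusted p = 1.8e-15, adjusted p = 0.470 with an estimated correlation). They took 13.2 ± 6.32% of counts in OE and 40.1 ± 14.7% in KO tumors (SD, n = 4 each, exact permutation p = 0.0286, the smallest possible), and KO replicate 1 was highest at 61.8%. The median of the list stayed negative without any 1 library (-2.37 to -1.46), whereas the number of its genes that passed edgeR's test fell to 0 without OE replicate 1, 3 or 5 or KO replicate 3 or 4. Nuclear-encoded genes of oxidative phosphorylation did not pass (0 higher and 1 lower of 21, 1 and 1 adjusted over the list alone, median -0.39, camera adjusted p = 0.476), and NDUFB3 had -2.31 (SE 0.52).

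**Figure D3:**
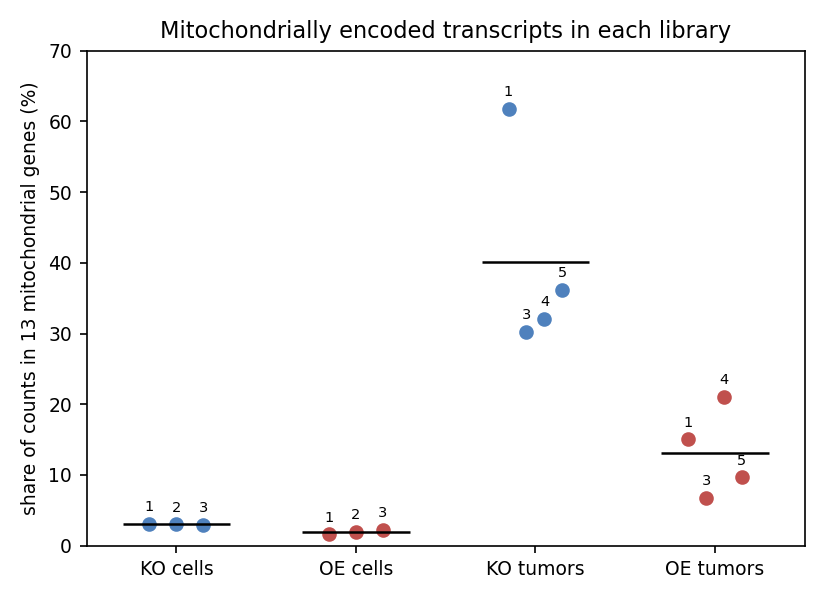
Percent of all counts in the 13 mitochondrially encoded genes in each library; points are libraries with their replicate numbers and lines are group means. The means are 1.95% in OE and 3.05% in KO cells and 13.2% in OE and 40.1% in KO tumors.

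Hypoxia response genes rose in 4 of 27 cases in OE tumors and fell in 0 (16 and 0 adjusted over the list alone, median 1.18, camera adjusted p = 6.9e-08, adjusted p = 0.519 with an estimated correlation). These were VEGFA, the glucose transporter SLC2A3 (2.21, SE 0.49), DDIT4 (1.45, SE 0.30) and ERO1A (1.31, SE 0.29). ATF4 and amino acid response targets had 1 higher of 24, DDIT4, and 0 lower (6 and 0 adjusted over the list alone, median 0.70, camera adjusted p = 0.0021, adjusted p = 0.299 with an estimated correlation). Ribosomal protein genes had 0 changed of 25 by edgeR's test and 0 adjusted over the list alone, but a positive median of 0.83 (camera adjusted p = 0.0088, adjusted p = 0.519 with an estimated correlation, and 0.266 without OE replicates 3 and 5). Wnt targets rose in 2 of 17 cases and fell in 0 (5 and 0 adjusted over the list alone, median 0.54, camera adjusted p = 0.0220), namely NKD1 (1.73, SE 0.39) and NOTUM (1.49, SE 0.34), both feedback inhibitors of the pathway. For Wnt targets, adjusted p = 0.519 with an estimated correlation, and the call was lost without OE replicate 5 (0.0502) or KO replicate 3 (0.0781). DNA and histone methylation enzymes had 0 changed of 21 and 0 adjusted over the list alone, with a median of 0.66 (camera adjusted p = 0.0466, adjusted p = 0.519 with an estimated correlation). Their call was lost without OE replicate 5 (0.0829), KO replicate 3 (0.0893) or KO replicate 4 (0.0697).

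Of the lists of liver functions, 2 passed in tumors, both lower in OE. Hepatocyte secreted proteins and regulators had 1 lower of 30, the fibrinogen chain FGA (-1.62, SE 0.31), and 0 higher (1 higher and 12 lower adjusted over the list alone, median -0.55, camera adjusted p = 0.0048, adjusted p = 0.519 with an estimated correlation). Bile acid and xenobiotic genes rose in 0 and fell in 3 of 22 cases (2 and 7 adjusted over the list alone, median -0.51, camera adjusted p = 0.0465, adjusted p = 0.519 with an estimated correlation). These were UGT1A1 (-2.10, SE 0.32), CYP3A5 (-2.41, SE 0.52) and CYP3A7 (-1.85, SE 0.41). That call was lost without OE replicate 3 (0.0579), OE 5 (0.0829), KO 3 (0.0962) or KO 4 (0.0561). Macrophage and leukocyte markers had 1 lower of 9, CD14 (-1.84, SE 0.42), and 0 higher (0 and 2 adjusted over the list alone, median -0.92, camera adjusted p = 0.0466, adjusted p = 0.470 with an estimated correlation). Their call was lost without OE replicate 1 (0.0578), OE 4 (0.0820), OE 5 (0.0607), KO 1 (0.0744), KO 3 (0.0526) or KO 5 (0.0550). A replicate block ended the calls of the bile acid list and the leukocyte markers (camera adjusted p = 0.0635 for both). Removing the GC trend ended these 2 and those of Wnt targets and methylation enzymes (0.0702 for all 4). Leaving out OE replicates 3 and 5 ended those of the bile acid list and the methylation enzymes (0.266 for both) and of the leukocyte markers (0.0740).

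Markers of fibroblasts, endothelium and leukocytes had negative medians in OE tumors, with overlap between the groups. A score of 26 fibroblast, endothelial and leukocyte markers was -0.341 ± 0.411 in OE and 0.341 ± 0.202 in KO tumors (SD, n = 4 each, exact permutation p = 0.0571, where 0.0286 is the smallest possible). Fibroblast markers had 0 changed of 10 by edgeR's test and 0 adjusted over the list alone (median -0.72, camera adjusted p = 0.0784), and passed without OE replicate 1 (0.0423) or KO replicate 4 (0.0476). Endothelial markers had 0 changed of 7 and 0 adjusted over the list alone (median -0.48, camera adjusted p = 0.419). Whether mouse reads were taken out is not given in the sources used here. The ANKRD30BL row took 16.1 ± 9.84% of counts in OE and 4.41 ± 2.33% in KO tumors (SD, n = 4 each, exact permutation p = 0.0857), led by OE replicates 3 (27.1%) and 5 (19.8%). IGF2, a fetal growth factor, took 14.3 ± 4.85% and 4.02 ± 1.18% (SD, n = 4 each, exact permutation p = 0.0286, the smallest possible). Without OE replicates 3 and 5, a choice made after seeing the data, 4 genes passed in tumors.

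Of the lists of methyl group metabolism, those besides the methylation enzymes above did not pass in tumors. Methionine cycle and transsulfuration genes had 0 changed of 15 by edgeR's quasi-likelihood test and 0 adjusted over the list alone (median 0.06, camera adjusted p = 0.866). MAT1A, the liver enzyme that makes S-adenosylmethionine, had -0.95 (SE 0.27) without passing. Folate genes had 1 lower of 19, DLD (-1.71, SE 0.30), and 0 higher (0 and 1 adjusted over the list alone, median 0.63, camera adjusted p = 0.830). Choline and betaine genes had 1 higher of 21, DMGDH, and 0 lower (1 and 0 adjusted over the list alone, median 0.36, camera adjusted p = 0.553). Polyamine genes had 0 changed of 10 (2 higher and 0 lower adjusted over the list alone, median 0.19, camera adjusted p = 0.508). Imprinted genes had PEG3 (2.59, SE 0.53) and IGF2 (1.63, SE 0.36) higher and 0 lower of 12 (3 and 5 adjusted over the list alone, camera adjusted p = 0.911), with a median of -0.23, a mean of 0.18 and a test pointing up. Genes silenced by DNA methylation were too few for a test (4, median -0.32). The medians of the imprinted and the silenced genes turned positive under library size alone.

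Of the other lists that did not pass in tumors, immediate early genes came nearest (0 changed of 13, 5 higher and 1 lower adjusted over the list alone, median 0.72, camera adjusted p = 0.0518). They passed without OE replicate 1 (0.0262), OE 4 (0.0292) or KO 4 (0.0464). Proliferation genes had 0 changed of 23 (0 adjusted over the list alone) and a median of 0.22 (camera adjusted p = 0.554), with MKI67 at -0.07 (SE 0.19). NRF2 targets had ABCC1 higher (1.35, SE 0.26) of 21 (2 higher and 0 lower adjusted over the list alone, median 0.44, camera adjusted p = 0.253), and cholesterol genes 0 changed of 19 (median -0.51, 0.333). Fatty acid synthesis genes had 0 changed of 16 (3 higher and 4 lower adjusted over the list alone, 0.901), with a median of 0.32, a mean of 0.11 and a test pointing down. Fatty acid oxidation genes had EHHADH lower (-2.33, SE 0.49) of 19 (2 and 4 adjusted over the list alone, median -0.07, 0.599). Interferon-stimulated genes had 0 changed of 20 (1 and 1 adjusted over the list alone) and did not pass (median -0.50, camera adjusted p = 0.20). HLA class I genes had 0 of 10 (median -0.41, 0.419). Inflammatory genes had HAMP, the iron hormone, higher (2.73, SE 0.44) of 13 (1 and 3 adjusted over the list alone, median -0.42, 0.419). Mesenchymal genes had SNAI2 lower (-2.25, SE 0.51) of 19 (2 and 3 adjusted over the list alone, median -0.56, 0.419), and p53 targets TP53INP1 lower (-1.36, SE 0.27) of 14 (0 and 1 adjusted over the list alone, median -0.19, 0.419). Urea cycle genes had 0 changed of 14 (0 and 3 adjusted over the list alone, median -0.10, camera adjusted p = 0.419), and unfolded protein response targets 0 of 15 (median 0.69, 0.316). Skeletal muscle (4, median 0.26, mean -0.14), adipocyte (3, -0.03), erythroid (1, 0.84) and keratinocyte markers (2, -0.23) were too few for a test. Under library size alone the medians of the fatty acid oxidation, urea cycle, p53, adipocyte and keratinocyte lists turned positive.

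The last comparison asked whether OE against KO effects were shared by cells and tumors. Of 7037 genes tested in both, 32 passed in both with the same direction, 12 higher and 20 lower, where independent lists give 5.12 and 8.41 (Fisher's exact test p = 0.0038 and 1.7e-04). Of the 32, 1 was BHMT and 10 were mitochondrially encoded, and without these 21 genes passed with the same and 20 with opposite directions. Fisher's test takes genes as independent, which the mitochondrially encoded ones are not. The others included ARFGEF3, an exchange factor family member (3.32 in cells and 1.60 in tumors, SE 0.17 and 0.29), DDIT4, a stress-induced inhibitor of mTOR (1.30 and 1.45, SE 0.18 and 0.30), MEGF6 (2.78 and 3.11) and GPAT3 (1.43 and 2.15). SDC4, a syndecan (-1.60 and -1.17, SE 0.05 and 0.19), FAXDC2 (-1.85 and -1.74), CYP3A7 (-1.48 and -1.85) and ACOX2 (-1.04 and -1.65) were lower in both. The tumor call of each of these 8 genes was lost in 4 to 6 of the 8 fits without a tumor library. Without 1 library the count of 32 became 7 (tumor OE replicate 1), 2 (OE 3), 214 (OE 4), 2 (OE 5), 12 (KO 1), 2 (KO 3) or 2 (KO 4). Under library size alone it was 66, of which 80.3% were higher against 37.5% of the 32. Across all 7036 genes besides BHMT, log2 fold changes correlated with r = 0.054 (rho = 0.060), and across the 482 with 1 annotated transcript with r = 0.222 (rho = 0.186), where genes are not independent replicates. Without the mitochondrially encoded genes these values were r = 0.050 (rho = 0.056) over 7023 genes and r = 0.187 (rho = 0.137) over 469.

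The effect of OE against KO differed between the systems in 378 of 8008 genes by edgeR's quasi-likelihood test of the interaction, 182 higher and 196 lower in tumors. MYL9 and GPC3, the lowest genes of OE cells, had 0.29 (SE 0.32) and -0.18 (SE 0.29) in tumors, differences of 7.91 (SE 0.58) and 7.28 (SE 0.52). SSTR5 and HOXD4, the highest of OE cells, had -0.75 (SE 0.30) and -0.18 (SE 0.45), differences of -5.85 (SE 0.50) and -4.27 (SE 0.62), and both have 1 annotated transcript. KCNC1, SORCS2 and IPO5 had differences of 6.03, 5.44 and 5.49 (SE 0.54, 0.52 and 0.93). These 7 genes passed in each of the 14 fits that left out 1 library. NT5E passed in both systems with opposite signs (3.40 and -2.44, SE 0.48 and 0.40), as did BPIFB2 (2.32 and -1.12), DHRS2 (1.27 and -2.27), COCH (1.30 and -2.79), MSH6 (1.28 and -4.65) and PDE11A (-1.36 and 1.67), among 20 such genes where independent lists give 13.4. The tumor call of each of these 6 named genes was lost in 2 to 5 of the 8 fits without a tumor library. The MSH6 call in cells was lost without OE replicate 2 or 3 or KO replicate 1 or 3 (0.109, 0.0622, 0.105 and 0.0950 by edgeR). So were those of MEGF6 without OE 2 or KO 1 (0.0512 and 0.0686) and GPAT3 without OE 2, OE 3 or KO 2 (0.0782, 0.0641 and 0.0784).

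Of 27 lists tested for the difference, mitochondrially encoded transcripts passed, with a median difference of -1.55 (camera adjusted p = 4.6e-05, adjusted p = 0.814 with an estimated correlation). Hypoxia, NRF2 and Wnt targets each had 0.155, and the methionine and hepatocyte lists 0.243. The count of 378 became 177, 167 and 192 without cell OE replicates 1, 2 and 3, 161, 165 and 181 without cell KO replicates 1, 2 and 3, 1349 without tumor OE 4 and 232 without tumor OE 5. Higher genes made up 48.1% of the 378, and 92.2% of 888 under library size alone. Other alternatives gave 75 (marker score as a covariate), 157 (replicate block), 230 (without tumor OE 3 and 5), 664 (voom) and 1037 (DESeq2). The symbols of both tables had levels that correlated across genes with r = 0.831 where a gene has 1 annotated transcript, and r = 0.149 where it has 10 or more, so differences between the tables are less certain for genes with many transcripts.

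**Figure D4:**
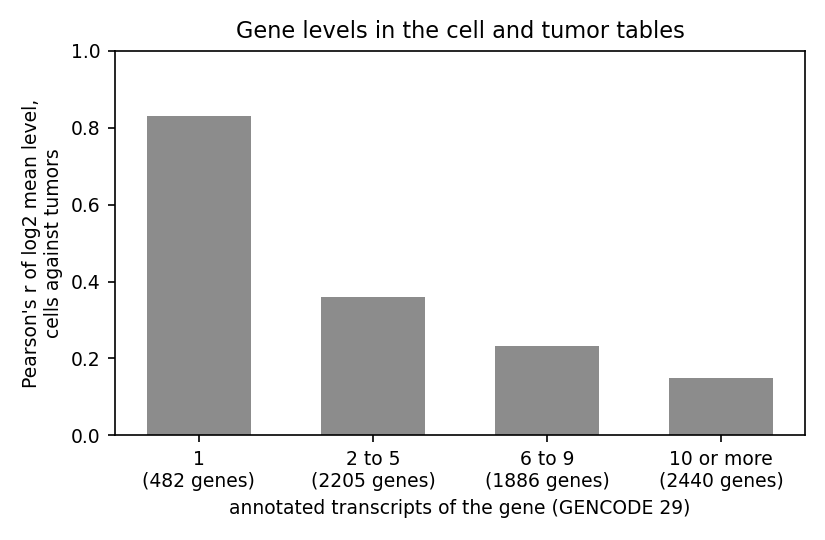
Pearson correlation (bars) between the cell and the tumor table of log2 mean level per gene symbol, by the number of transcripts annotated for the gene (482, 2205, 1886 and 2440 genes). The correlation falls from 0.831 for 1 transcript to 0.149 for 10 or more.

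A segment of chromosome 14, chosen after its values were seen, moved as a block and in opposite directions in the systems. The 84 tested genes that start below 40 Mb had a median log2 fold change of 0.53 in cells, 76 of them (90.5%) above 0, and 42 passed edgeR's test, all higher in OE. In tumors, 117 genes of the segment had a median of -1.34, 99 of them (84.6%) below 0, and 36 of the 117 lower genes that passed lay there. The 36 became 12 without OE replicate 1, 6 without OE 3, 59 without OE 4, 0 without OE 5, 9 without KO 1, 0 without KO 3 and 1 without KO 4, and the median stayed at -1.46 to -1.25. The count was 17 under library size alone (median -0.98), 0 with the marker score as a covariate (-1.14) and 0 without OE replicates 3 and 5 (-1.17). Genes from 40 to 60 Mb had medians of 0.03 and -0.06. Of the 196 genes with a lower effect in tumors, 40 lay in the segment, as did 14 of the 20 genes with opposite signs, DHRS2 and COCH among them. Per library, the segment's median stood at 0.258 ± 0.0153 in OE and -0.265 ± 0.0508 in KO cells (SD, n = 3 each), and at -0.575 ± 0.268 in OE and 0.646 ± 0.115 in KO tumors (SD, n = 4 each). No p is given for the segment, since it was picked for this shift.

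**Figure D5:**
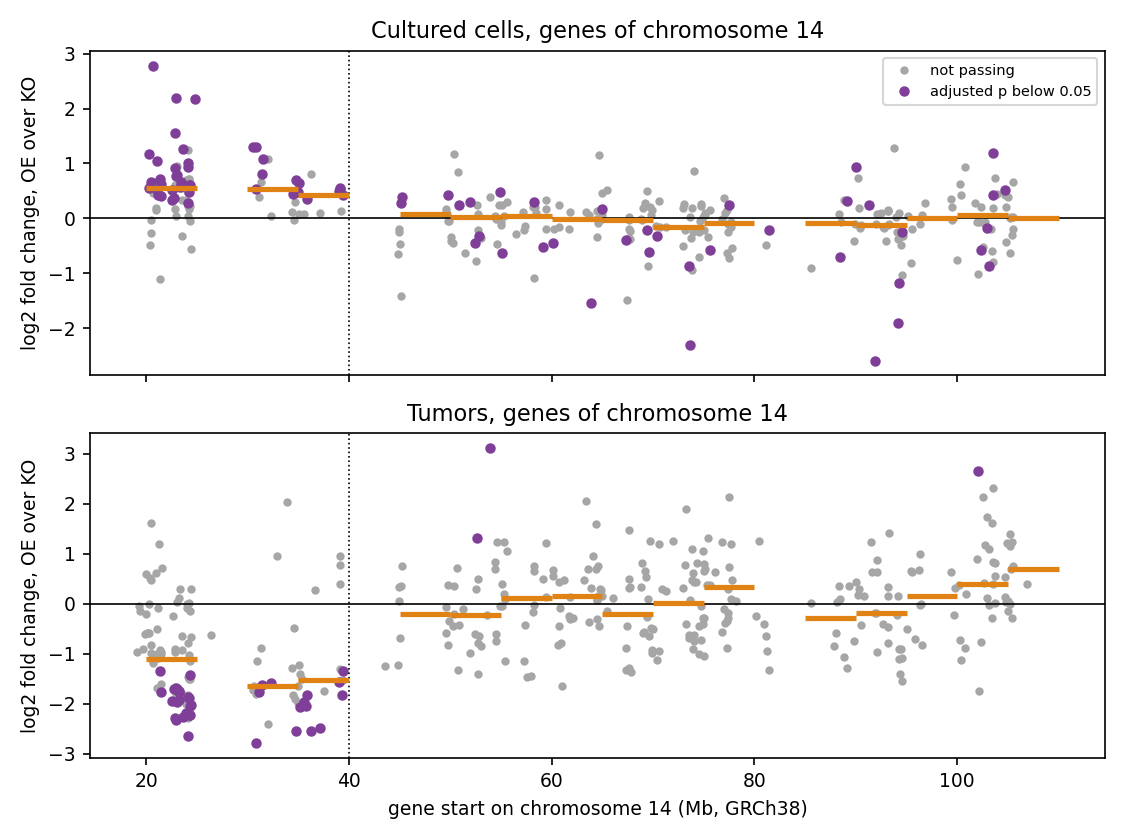
Log2 fold change (OE over KO) of genes on chromosome 14 by gene start in Mb, in cells and in tumors; points are genes, purple where edgeR's test passed, orange lines are medians of 5 Mb windows with at least 8 genes, and the dotted line marks 40 Mb. Below 40 Mb the median is 0.53 in cells and -1.34 in tumors.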

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

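Of the tests in this part, those on scaling, stromal RNA and KO replicate 1 for mitochondrially encoded transcripts, both tests on levels of the same symbol the tests on the dose and the shared copy number of the chromosome 14 segment and the 70 tumor labellings with the real cell split were chosen after their results were seen.

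In 8 of 174 groups of 4 tumor libraries, 1 library stood far from the other 3, where chance gives about 1 in 20 (8.7). KO replicate 1 had the highest mean of mitochondrially encoded transcripts, 15.51 log2 CPM against 13.86 to 13.95, and the lowest METTL9, 2.90 CPM against 4.39 to 4.48. KO replicate 4 had the highest mean of immediate early genes, 4.64 log2 CPM against 4.40 to 4.43, and KO replicate 3 the lowest DDIT4, 51.5 CPM against 78.4 to 82.2. OE replicate 3 had the lowest mean of urea cycle genes, 3.14 log2 CPM against 3.37 to 3.40. HOXD4 was highest in OE replicate 1, 12.7 CPM against 3.80 to 4.17, IRX3 in OE replicate 5, 10.5 CPM against 3.85 to 4.41, and LPCAT2 in OE replicate 4, 87.1 CPM against 34.0 to 42.0.

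Among BHMT and the genes named across both systems, and beside others of the 378 genes, the OE against KO effect differed between tumors and cells in 15 by a test of the difference itself, as it did for 1 list. Of these genes 10 were named for the highest or lowest values of that same test and others for opposite signs in the systems, so their passing is no separate finding. Effects were lower in tumors for BHMT (log2 difference -3.41), SSTR5 (-5.85), HOXD4 (-4.27), NT5E (-5.88), MSH6 (-5.97), COCH (-4.15), DHRS2 (-3.60), BPIFB2 (-3.50) and ARFGEF3 (-1.78). They were higher for MYL9 (7.91), GPC3 (7.28), KCNC1 (6.03), IPO5 (5.49), SORCS2 (5.44) and PDE11A (2.98). Adjusted p ranged from 1.8e-06 for MYL9 and GPC3 to 0.0262 for BHMT by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Mitochondrially encoded transcripts had a median difference of -1.55 (camera adjusted p = 4.6e-05, adjusted p = 0.814 with an estimated correlation).

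Mitochondrially encoded transcripts were lower in OE in both systems. The scaling of the libraries is argued against, as the median of the list was -0.61 or lower under 3 scalings in both systems. KO replicate 1 as the whole cause in tumors is argued against by a median of -1.46 without it. With the marker score as a covariate the tumor median was -1.95, against -2.11 without the score, and 0 instead of 12 of the 13 genes then passed edgeR's test by themselves. This cannot decide on stromal and leukocyte RNA, since the score was not shown to measure it. Leukocyte and fibroblast markers had negative medians in cultured OE cells too (-0.58 and -0.44). Stromal and leukocyte RNA in tumors thus stays open. Also open are an effect of BHMT, a difference between the OE and KO cell lines that has nothing to do with BHMT, the blasticidin given to OE cells, and a difference in how samples were handled, and these were not tested.

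The genes of chromosome 14 that start below 40 Mb shifted together, upward in OE cells and downward in OE tumors. A GC trend as the cause is argued against, since the median in tumors was -1.38 after the linear trend over all other genes was removed. Copy number of the segment that cells and tumors share is argued against as the only cause of both shifts, by the opposite signs of the medians, 0.53 and -1.34. As a part of the cause it stays open, since the segment was picked for these shifts. Rows that hold different transcripts stay open for cells, where only 2 genes of the segment have 1 annotated transcript (median 0.13). A dose of the segment that differs between OE and KO with opposite signs in cells and tumors stays open and needs DNA data, as the share of at least 84.6% of genes moving the same way follows from the choice of the segment.

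The same symbol often had different levels in the cell and the tumor table. A row that holds 1 transcript of its gene, not always the same in both tables, is a candidate explanation, as levels correlated with r = 0.149 for genes with 10 or more annotated transcripts. A difference between tumors and cultured cells that reaches all genes alike is argued against, since r was higher by 0.682 for genes with 1 annotated transcript. A biological difference tied to the number of transcripts was not tested.

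Other splits of the same libraries tested whether chance can give counts as large. In cells, the 10 splits of 6 libraries are too few for a share under 0.05, where the real split gave 1870 genes and the highest other 0 (1 split as large, the real one), and the real split gave 17 lists and the highest other 7 (1 split). In tumors chance cannot be excluded, as 2 of 35 splits gave as many genes, the real 179 and another 479, and 2 of 35 as many lists, the real 9 and another 10. The split with 479 genes set OE replicates 1, 3 and 5 and KO 5 against OE 4 and KO 1, 3 and 4, so it exchanged OE 4 and KO 5. It also parted the 4 libraries whose levels correlated highest with GC content (r = -0.0788 to 0.323) from the 4 lowest (-0.236 to -0.114), a structure of the samples whose part in the 479 was not tested. For the difference between the systems, 1 of 100 splits drawn in both systems at once was as large, the real one (378 genes, highest other 99). The other draws gave 31 to 99 genes with the real cell split and 0 to 10 without it. The count was thus lower without the real cell labels, whose 10 splits are too few, so these draws do not exclude chance. It was lower with other tumor labels too in these draws, at 31 to 99 genes against 378. With the real split of the cells, 4 of the 70 tumor labellings gave as many genes (highest other 612), namely the real tumor split and the split with 479 genes, each with its sides named either way, so chance in the tumor labels is not excluded. For genes called in both with the same direction the splits decide nothing (1 of 100 drawn, 32 genes, highest other 0, and 3 of 70 with the real cell split, highest other 48), since 33 of 35 tumor splits called 0 genes by edgeR.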

How the results depend on the processing

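Of the alternatives in this part, leaving out OE tumor replicates 3 and 5 together, removing the GC trend and keeping only genes with 1 annotated transcript were chosen after seeing the data.

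No named gene or list that passed its test changed direction under the alternatives run for it. Library size alone, which was not run for the list tests, turned tumor list medians only of lists that did not pass or were not tested. BHMT passed in tumors under all 19 alternatives (log2 fold change 7.79 to 8.91) and in cells under all 15 but voom, where it had 11.69 (SE 3.73, adjusted p = 0.0779, against a range of 6.0e-74 to 0.0779). The 10 genes named for the difference kept their calls in all 242 values, and named cell genes stayed on their side of the threshold in 1956 of 2142, with 184 weaker and 2 newly past it. Named tumor genes stayed on theirs in 1614 of 2097, with 430 weaker and 53 newly past it. For all counts below the cause was not tested, except where fewer genes or libraries entered.

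Scaling by library size alone gave 486 genes in tumors against 179, 888 for the difference against 378 and 66 in both systems against 32. DESeq2 gave 1220, 1037 and 155, voom 664 for the difference, and a stricter filter 275 in tumors. A replicate block gave 110, 157 and 17, and the labels do not say whether the replicate numbers pair OE and KO libraries. Deviations from the group mean correlated at r = -0.217 to 0.181 in same-numbered tumor pairs and at -0.350 to 0.301 in others. With 4 same-numbered pairs these ranges do not decide whether tumors were paired. All 14 libraries in 1 fit gave 172 in cells and 1512 in tumors, and for the difference that fit is the main one, so it was not run again. The marker score as a covariate gave 1 in tumors, 75 and 1, and without OE tumor replicates 3 and 5, with fewer libraries, the counts were 4, 230 and 2. Among genes with 1 annotated transcript, where fewer were tested, 219 passed in cells, 39 in tumors, 53 for the difference and 14 in both. An adjusted p below 0.01 gave 937, 5, 107 and 1, and a 2-fold minimum 465 in cells and 9 in both. Alternatives for normalized values were not run, as the tables hold counts.

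Of the lists, 0 passed in cells and 0 in tumors with an estimated correlation, and in tumors 2 passed fry, 5 without OE replicates 3 and 5, and 5 after the GC trend was removed.

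Leaving out 1 library gave 1249 to 1875 genes in cells, 5 (without KO 3) to 2056 (without OE 4) in tumors, 161 (without cell KO 1) to 1349 (without tumor OE 4) for the difference and 2 (without tumor OE 3, OE 5, KO 3 or KO 4) to 214 (without OE 4) in both. Lists numbered 13 to 17 in cells and 5 (without OE 5 or KO 3) to 10 in tumors. Tumors held 3269865 to 7235182 counts per library against 10830526 to 13382570 in cells, and had a coefficient of variation between libraries of 0.414 against 0.216. How much depth and spread each lower the tumor counts was not tested.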

Other observations

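Within each tumor library, the deviation of a gene's log2 level from its mean over the 8 tumors correlated with the GC content of its transcripts at r = 0.169, 0.323, -0.114 and 0.201 in OE replicates 1, 3, 4 and 5 and -0.195, -0.218, -0.236 and -0.0788 in KO replicates 1, 3, 4 and 5. Across genes, log2 fold change correlated with GC content with r = 0.295 in tumors and -0.014 in cells. Medians of 10 Mb bins correlated between cells and tumors with r = -0.077 over 181 bins, where a DNA copy number that cells and tumors share calls for a positive r. That value was set by the 2 bins of the chromosome 14 segment, and r was 0.205 over the other 179 bins, so shared copy number outside the segment stays open.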
